A study of Mus musculus with 18 samples.

How the data were processed

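Bulk RNA-seq of whole quadriceps from 18 mice in 6 groups was examined, with 1 library per mouse. Per the labels, RNA was extracted with TRIzol, 1 ug entered an Illumina Stranded mRNA library preparation, and libraries were read on a NextSeq 2000 as pairs of 58 bp reads. The authors mapped the reads to mm10; the aligner and the counting tool are not stated. Each deposited library holds, per the file headers, total and unique exon reads as counts, an exon length and an RPKM for 48709 genes. Of these genes, 17044 carry an exon length of 0 and no read, which left 31665. Whether a count stands for a read or a read pair is not stated. The deposited RPKM values are the counts divided by exon length and by 1 constant per library, to within a relative 5.3e-05 in untreated dyW replicate 1 and 2.8e-09 or less in the other libraries, and exon reads made up 91.48% to 94.86% of that constant, so the authors' divisor also holds reads outside exons. The authors also deposited 2 tables of their own comparisons, with a log2 fold change, a p-value and an FDR-adjusted p-value per gene; their test is not stated, and their tables are used below only where they are named. Gene symbols, identifiers and positions are those deposited by the authors, and 87.8% of the listed genes have the same span in GENCODE M21.

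The depth ranged from 15.8 to 45.2 M (mega) exon reads per library, and unique reads made up 97.97% to 98.39% of them. Libraries were grouped by the genotype, treatment and cohort in their labels. The untreated cohort had 7 libraries and the treatment cohort had 11. Each library carries its own animal number in the labels, and samples were not paired.

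Gene counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test, after TMM normalization and filterByExpr (minimum count 10, minimum total count 15), with Benjamini-Hochberg adjustment, a threshold of adjusted p under 0.05 and no fold cutoff. Every adjusted p given for a gene is from edgeR unless another tool is named. The untreated cohort was fitted alone. The treatment cohort was fitted as 4 groups that share an estimate of the spread, from which the contrasts between groups and the difference between the TD139 effects in dyW and WT were taken. The difference between the genotype effects of the 2 cohorts was fitted on all 18 libraries in 6 groups. Standard errors are those of the fitted log2 fold change. Levels are given as mean RPKM ± SD between mice; RPKM is not corrected for differences in composition, so a ratio of RPKM means differs from the fitted fold change.

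There were 40 gene lists, covering galectins, laminins and their receptors, matrix, immune and stromal cell types, fibre types, metabolism, stress, and cell types from neighbouring tissue, written from textbook knowledge. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 40 lists of a comparison. Members past the threshold were counted with p adjusted over all genes tested and adjusted over the list alone. The named genes are Lama2, Lama1 and Lgals3; up to 8 genes per direction with the largest fold change among those past the threshold, with a mean RPKM of at least 1 in the higher group and no overlap between the groups; and up to 4 members per list with the smallest p. Except for list members, genes with a provisional or numbered symbol (such as Gm numbers and Rik clones), pseudogenes and ribosomal-like loci were not named, also where their fold changes were larger; overlap was judged on log2 expression after TMM scaling. Where fewer than 8 passed, the genes with the smallest p filled up to 5 per direction. For the differences between effects, the rule took the 5 smallest p in each direction among genes with a mean RPKM of at least 1 in a group. Genes named outside this rule are given as chosen after their values were seen.

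To relate the treatment to the disease profile, genes past the threshold in the untreated cohort with a log2 fold change of at least 1 (2117 higher, 1368 lower) were taken as sets into the treatment cohort, which shares no library with it. A disease score per library was the mean log2 expression (prior count 2) of the first set minus that of the second, compared by an exact two-sided permutation test. Genes at 0 in all libraries of a group were given a lower bound from a floor of 3 reads over the group; ratios over 1 to 3 reads carry a 95% exact Poisson interval. Floors and intervals cover counting error only.

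The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, RLE size factors, no filter beyond 1 read in 1 library, limma on log2(RPKM + 0.1) and log2(RPKM + 1), a further fold cutoff, the sex label as a term, other sets of libraries in the fit, and leaving out each library of the groups compared in turn. Added after seeing the data were unique reads in place of total reads, the level of Xist as a term, the untreated cohort without dyW replicates 3 and 4, DESeq2 on the dyW TD139 and dyW PBS groups alone, and the list tests without single libraries. Other splits of the same libraries into groups were refitted where each group had at least 3 libraries; for the difference between cohorts, 100 arrangements out of 700 were drawn, each once; an earlier draw of 60 had repeated arrangements and was replaced. The procedure was tested on simulated counts with known changes: in the comparison of TD139 with PBS in dyW, 32% of genes with a log2 fold change of 1 and 76.8% of those with 2 were called in the right direction, and in the untreated comparison 42.9% and 84.8%. No gene was called in simulated data without changes. The simulated genes varied independently of each other, without differences between libraries that many genes share, so these shares may not carry over to the real data. Figures were drawn with matplotlib 3.10.9.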

Results

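The dyW mouse is deficient in the laminin alpha 2 chain and is a model of LAMA2-related congenital muscular dystrophy; the wild type (WT) mice were C57BL/6J. TD139 is an inhibitor of galectin-3, a sugar-binding protein secreted by macrophages and other cells, and PBS was its vehicle by the group names. Quadriceps came from untreated WT (n = 3) and untreated dyW (n = 4) mice, and from WT PBS (n = 3), dyW PBS (n = 3), dyW TD139 (n = 3) and WT TD139 (n = 2) mice. The untreated mice carry an age label of 5 weeks and the others one of 3 weeks, while the protocol of both cohorts places the tissue collection at 5 weeks, so the age of the treated mice is not certain. Dose, route and duration of TD139 are not in the labels. Depth was 32.9 to 37.7 M exon reads per library in untreated WT, 35.7 to 45.2 in untreated dyW, 35.2 to 42.6 in WT PBS, 15.8 to 38.9 in dyW PBS, 38.7 to 39.6 in dyW TD139 and 33.1 to 34.2 in WT TD139.

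The first comparison asks how dyW muscle differs from healthy muscle at 5 weeks. Lama2 (ENSMUSG00000019899, mm10 chromosome 10, 26980036 to 27619758), the targeted gene, was lower in dyW, at 0.707 ± 0.119 RPKM (n = 4) against 4.75 ± 0.279 (n = 3; log2 fold change −3.29, SE 0.19, adjusted p = 6.7e-05). Lgals3 (ENSMUSG00000050335, chromosome 14, 47367751 to 47386160), which encodes galectin-3, was higher in dyW, at 47.9 ± 12.2 RPKM (n = 4) against 1.65 ± 0.317 (n = 3; log2 fold change 4.30, SE 0.23, adjusted p = 4.75e-05). In both genes the 4 dyW libraries lay apart from the 3 WT libraries. Lama1, the paralog of Lama2, had too few reads to be tested. Lists of regenerating fibre, macrophage, antigen presentation and matrix genes were higher in dyW, and fast fibre and glycogen genes were lower. None of the 40 lists passed with an estimated correlation (smallest adjusted p = 0.393 by camera), and the neutrophil, lymphocyte and mast cell lists did not pass at the preset correlation. Of 14846 genes tested, 3671 were higher and 3724 lower, or 49.8% of the total.

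**Figure D1:**
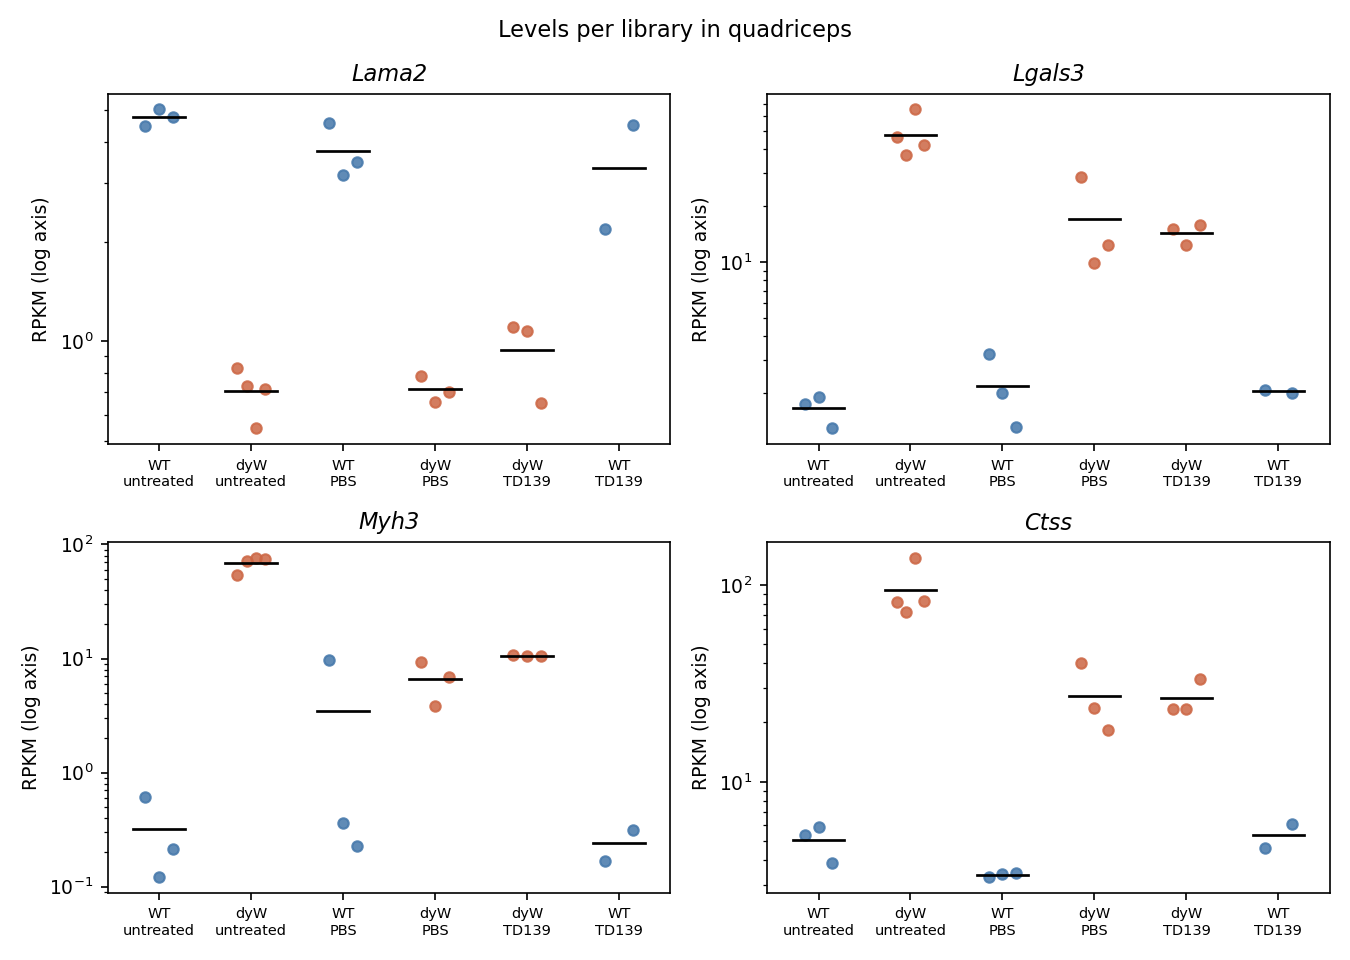
RPKM per library (points, log axes) and group means (lines) of Lama2, Lgals3, Myh3 and Ctss in the 6 groups, WT in blue and dyW in orange. Lama2 was at most 1.10 RPKM in the dyW libraries and at least 2.18 in the WT libraries, and Myh3 of WT PBS replicate 1, at 9.72 RPKM, lay among the dyW libraries of its cohort.

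Among the genes with the largest rises in untreated dyW muscle were the embryonic myosin heavy chain gene Myh3 (0.318 ± 0.263 RPKM in WT, 69.0 ± 10.4 in dyW, log2 fold change 7.26, SE 0.53) and Sln, which encodes sarcolipin, a regulator of the calcium pump (log2 fold change 7.04, SE 0.57). Msln, encoding mesothelin, had a log2 fold change of 6.94 (SE 0.53). Sprr1a, Gdf1 and R3hdml had no reads in the WT libraries and were at least 81.5-fold, 75.1-fold and 57.2-fold higher in dyW. Gdf1 had a value in only 9 of 16 alternative settings, and 1 of these ended its call (adjusted p = 0.0702). Chil3, a macrophage chitinase-like gene, had 2 reads over the WT libraries and 735 over the dyW libraries, a depth-scaled ratio of 243 (95% exact Poisson interval 66.9 to 2010). The ratio rests in large part on dyW replicate 1, at 7.19 RPKM against 0.482 to 1.34 in the other dyW libraries, without which the fitted log2 fold change of Chil3 went from 7.15 to 5.54. Cldn2, a tight junction gene, had 3 and 649 reads, a ratio of 143 (48.6 to 694). Among genes with an established symbol, a mean of at least 1 RPKM in WT and no overlap between the groups, the largest falls were in Nt5c1a, a cytosolic nucleotidase (log2 fold change −5.19, SE 0.69), the S-adenosylmethionine decarboxylase genes Amd2 (−5.09, SE 0.78) and Amd1 (−4.25, SE 0.67), the cadherin gene Cdh4 (−4.86, SE 0.65), Rsc1a1 (−4.74, SE 1.19), Cep85l (−4.45, SE 0.68), the kinase gene Hipk2 (−4.41, SE 0.52) and Lmbrd2 (−3.87, SE 0.46). The spread was wide in WT for Amd1, at 228 ± 227 RPKM, and Rsc1a1 had no reads in 3 dyW libraries and 0.683 RPKM in the other. The value of Rsc1a1 ranged from −11.11 to −1.83 over the alternatives, the latter by limma on log2(RPKM + 1), so the size of its fall is not firm. Rsc1a1 had a value in 15 of 16 alternatives, and its call was lost with DESeq2 (adjusted p = 0.138).

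Macrophage genes were higher in untreated dyW: 26 of 31 tested members rose and 2 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 2.17 (camera adjusted p = 2.98e-09; adjusted p = 0.393 with an estimated correlation). Trem2, a lipid receptor of macrophages, had a log2 fold change of 5.16 (SE 0.37), Mpeg1 of 4.03 (SE 0.21), the lysosomal protease genes Ctss of 3.65 (SE 0.24) and Lgmn of 1.94 (SE 0.16). Of 16 genes of dendritic cells and antigen presentation, 10 rose, and 11 adjusted over the list alone (median 1.98, adjusted p = 0.000355; adjusted p = 0.415 with an estimated correlation), among them H2-Eb1 at 2.42 (SE 0.37) and H2-DMa at 1.90 (SE 0.27). Complement genes rose in 12 of 18 and fell in 1, or 13 and 1 adjusted over the list alone (median 1.10, adjusted p = 0.000987; adjusted p = 0.393 with an estimated correlation). C1qa and C1qb were each at 2.11 and the anaphylatoxin receptor gene C3ar1 at 2.10. Of 28 chemokine and cytokine genes, 13 rose and 2 fell by both adjustments, over all genes and adjusted over the list alone (median 1.33, adjusted p = 0.00171; adjusted p = 0.393 with an estimated correlation). Il1rn was at 4.34, Cxcl10 at 3.83, Cx3cl1 at 3.44 and Cxcl16 at 2.68. Inflammasome and toll-like receptor genes rose in 19 of 27, also adjusted over the list alone (median 1.21, adjusted p = 1.16e-06; adjusted p = 0.393 with an estimated correlation). Tlr13 was at 2.82 and Nfkb2 at 1.76. Of 8 neutrophil genes 6 rose and 1 fell, also adjusted over the list alone, and the list did not pass (median 2.57, adjusted p = 0.163). The member that fell was Mmp9, a matrix protease of neutrophils and other cells (log2 fold change −2.36, SE 0.36). Among galectins and galectin-3 partners, 7 of 13 rose by both counts, including adjusted over the list alone (median 0.69, adjusted p = 0.00666; adjusted p = 0.393 with an estimated correlation). Besides Lgals3, these included Lgals4 at 1.69, Lgals1 at 0.92 and the hyaluronan receptor gene Cd44 at 1.57.

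Genes of the fibrillar matrix and fibrosis were higher: 35 of 47 rose and 1 fell, and 36 and 1 adjusted over the list alone (median log2 fold change 1.08, adjusted p = 8.06e-09; adjusted p = 0.393 with an estimated correlation). The TGF-beta binding protein gene Ltbp2 was at 4.33 (SE 0.26), Postn, encoding periostin, at 3.72 (SE 0.26), the proteoglycan gene Bgn at 2.53 (SE 0.14) and Tgfb1 at 1.83 (SE 0.13). Cilp, a cartilage matrix gene of the tendon and cartilage list, had a log2 fold change of 3.61 (SE 0.15), while that list did not pass (adjusted p = 0.991). In the basement membrane list 7 of 22 genes rose and 7 fell, or 7 and 8 adjusted over the list alone (adjusted p = 0.962): Lama4 rose (0.82, SE 0.11), and the collagen IV genes Col4a3 (−2.94, SE 0.40) and Col4a4 (−2.76, SE 0.28) fell. Among laminin receptors and the dystrophin complex 3 of 24 rose and 11 fell, also adjusted over the list alone, and the list did not pass (median −0.34, and 0.16 by limma on log2(RPKM + 0.1); adjusted p = 0.0648). The laminin receptor gene Bcam rose (1.87, SE 0.14), and the sarcoglycan genes Sgcd (−1.41, SE 0.15) and Sgcb (−1.05, SE 0.13) fell.

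Fibre genes moved in both directions. Embryonic and regenerating fibre genes rose in 19 of 24 and fell in 2, or 20 and 2 adjusted over the list alone (median 2.09, adjusted p = 1.05e-06; adjusted p = 0.393 with an estimated correlation). The embryonic light chain gene Myl4 was at 5.83 (SE 0.37) and perinatal Myh8 at 5.30 (SE 0.17). Fast fibre genes fell in 17 of 20, also adjusted over the list alone (median −1.21, adjusted p = 2.12e-05; adjusted p = 0.393 with an estimated correlation): the calcium buffer gene Pvalb was at −1.81, glycogen phosphorylase Pygm at −1.54, creatine kinase Ckm at −1.40 and Myl1 at −1.23. Glycolysis and glycogen genes fell in 19 of 24, and in 21 adjusted over the list alone (median −0.86, adjusted p = 1.05e-06; adjusted p = 0.393 with an estimated correlation), among them the phosphorylase kinase genes Phka1 (−2.43) and Phkg1 (−1.90) and the glycogen-targeting subunit genes Ppp1r3c (−2.19) and Ppp1r3a (−2.18). Slow fibre genes rose in 13 of 17, and in 14 adjusted over the list alone (median 2.95, adjusted p = 0.000131; adjusted p = 0.528 with an estimated correlation). Myl6b was at 3.39, Fhl2 at 2.95, Pln, encoding phospholamban, at 2.37 and Actn2 at 1.91. The slow myosin gene Myh7 differed among the dyW libraries, at 0.807 RPKM in replicate 1, and 236 and 291 in replicates 3 and 4. In WT it was at 10.1, 0.0092 and 1.08 RPKM in replicates 1, 2 and 3, so the groups overlapped. The median log2 level of the slow fibre list was taken against the mean of all 18 libraries. It was 0.26, −4.21 and −1.54 in the WT libraries and 0.63, 1.15, 2.42 and 2.49 in the dyW libraries. Without dyW replicates 3 and 4, 6106 genes passed in the whole comparison. Genes of denervated muscle did not pass as a list (adjusted p = 0.167), but the fetal acetylcholine receptor gene Chrng (4.60, SE 0.45), Runx1 (2.56, SE 0.15) and Ncam1 (2.05, SE 0.22) rose.

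Proliferation genes rose in 22 of 30 and fell in 1, or 22 and 2 adjusted over the list alone (median 1.04, adjusted p = 5.87e-05; adjusted p = 0.528 with an estimated correlation). Cdk1 was at 1.93, Rrm2 at 1.84 and Ccnb1 at 1.66, while Aurka fell (−1.28). Apoptosis and p53 target genes rose in 15 of 25 and fell in 2, or 16 and 2 adjusted over the list alone (median 0.63, adjusted p = 0.00373; adjusted p = 0.393 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a was at 3.00 and Eda2r at 1.39. Schwann cell and nerve genes rose in 13 of 17, and in 14 with 1 lower adjusted over the list alone (median 1.29, adjusted p = 4.18e-05; adjusted p = 0.393 with an estimated correlation). Of the myelin genes, Prx was at 2.15 and Cldn19 at 2.00. Cytosolic ribosomal protein genes rose in 51 of 78, and in 58 adjusted over the list alone (median 0.54, adjusted p = 2.88e-08; adjusted p = 0.528 with an estimated correlation). Rpl3 was at 1.52, Rps28 at 0.95 and Rps19 at 0.84. Across genes, which are not independent replicates, the log2 fold changes fell with log2 exon length (r = −0.22), and ribosomal protein transcripts are short. Of 13 mitochondrially encoded genes 4 fell, and 1 adjusted over the list alone (median −0.65, adjusted p = 0.00666; adjusted p = 0.528 with an estimated correlation); mt-Nd6 was at −0.95 and mt-Co3 at −0.57, and mt-Co3 ranged from −0.64 to −0.03 over the alternatives. The call was lost in 10 of 16 alternatives for mt-Co3 and in 2 of 16 for mt-Nd6. Genes of the unfolded protein and stress response rose in 10 of 22 and fell in 2, or 11 and 2 adjusted over the list alone (median 0.50, adjusted p = 0.0489; adjusted p = 0.528 with an estimated correlation), a call lost with RLE in place of TMM (adjusted p = 0.0501). Keratinocyte genes rose in 4 of 6, also adjusted over the list alone (median 1.11, adjusted p = 0.0258; adjusted p = 0.393 with an estimated correlation).

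The call counts of the untreated comparison rest on TMM scaling. Limma on log2(RPKM + 0.1), without that scaling, moved the median of all genes from 0.03 to 0.50 and called 84.7% of its genes as higher, and 4238 of the 7395 genes were called by both. The fast fibre, glycolysis and mitochondrially encoded lists kept a median below 0 on that scale as well. In the authors' own results 7141 genes passed an FDR-adjusted p under 0.05, 3508 higher and 3633 lower. Of these, 6869 were tested here, all with the same sign, and 6466 also passed here.

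The second comparison asks whether the dyW profile is present in vehicle-treated mice of the treatment cohort. Lama2 was again lower in dyW PBS, at 0.715 ± 0.0658 RPKM against 3.75 ± 0.731 in WT PBS (n = 3 each; log2 fold change −2.67, SE 0.28, adjusted p = 0.000912), and Lgals3 was higher, at 16.9 ± 10.1 against 2.18 ± 0.972 (n = 3 each; log2 fold change 2.65, SE 0.34, adjusted p = 0.0039). Among genes with an established symbol, a mean of at least 1 RPKM in the higher group and no overlap between the groups, the largest rises were in the aldehyde dehydrogenase gene Aldh3a1 (5.24, SE 0.71), the simple epithelial keratin genes Krt8 (5.19, SE 0.57) and Krt18 (4.21, SE 0.51), Ripply1 (4.33, SE 0.80), the chemokine gene Ccl8 (4.18, SE 0.70), the macrophage gene Mpeg1 (3.88, SE 0.32), Bcl2a1b (3.60, SE 0.68) and the metallothionein gene Mt2 (3.58, SE 0.47). The largest falls among such genes, besides Lama2, were in Cd28 (−2.72, SE 0.49), Rmi2 (−2.12, SE 0.39), Myo5c (−1.62, SE 0.36), Alpl (−1.54, SE 0.34), Arrdc2 (−1.53, SE 0.36), the sarcomeric ankyrin repeat gene Ankrd23 (−1.26, SE 0.26) and Magix (−1.19, SE 0.28). Many of these calls were lost in some of the 15 alternatives: in 10 for Magix, 9 for Alpl, 7 for Arrdc2, 6 each for Myo5c and Ankrd23, 5 for Bcl2a1b, 4 each for Ripply1 and Rmi2 and 2 for Cd28. Of 15331 genes tested, 368 were higher and 43 lower.

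In dyW PBS muscle 20 of 31 macrophage genes rose, and 25 adjusted over the list alone (median 1.66, adjusted p = 6.96e-23; adjusted p = 0.167 with an estimated correlation). Ctss was at 2.68, the F4/80 gene Adgre1 at 2.52 and Cybb at 2.03. Antigen presentation genes rose in 6 of 16, and in 13 adjusted over the list alone (median 1.87, adjusted p = 3.41e-14; adjusted p = 0.0517 with an estimated correlation, 0.0271 without dyW PBS replicate 1 and 0.118 without WT PBS replicate 1). Of the class II genes, H2-Aa was at 2.48, H2-Ab1 at 2.29 and Cd74 at 2.07. Complement genes rose in 9 of 18, and in 15 with 1 lower adjusted over the list alone (median log2 fold change 1.3, adjusted p = 1.27e-10; adjusted p = 0.0891 with an estimated correlation). C3ar1 was at 2.42, C1qa at 1.74 and C1ra at 1.28. Matrix genes rose in 8 of 47, and in 19 adjusted over the list alone (median 0.75, adjusted p = 9.54e-11; adjusted p = 0.337 with an estimated correlation). Postn was at 2.13, Lum at 1.40 and Mmp14 at 1.09. Interferon response genes rose in 2 of 34, and in 9 adjusted over the list alone (median 0.66, and 0.35 without dyW PBS replicate 1; adjusted p = 1.04e-08; adjusted p = 0.337 with an estimated correlation). Ifi27l2a was at 2.28 and Irf7 at 1.43. Embryonic and regenerating fibre genes rose in 12 of 24, and in 17 with 1 lower adjusted over the list alone (median 0.99, adjusted p = 9.53e-12; adjusted p = 0.01 with an estimated correlation). With an estimated correlation the call of this list was lost without WT PBS replicate 1 (adjusted p = 0.0829). Myl4 was at 3.46, the stretch-responsive gene Ankrd1 at 2.90 and fetal troponin Tnnt2 at 2.10. Of 13 galectins and partners 2 rose, and 3 adjusted over the list alone (median 0.23, and 0.41 without WT PBS replicate 1; adjusted p = 0.00138; adjusted p = 0.0891 with an estimated correlation); Lgals3bp was at 1.17, and Cd44 at 1.20 did not pass (adjusted p = 0.0543) but did in 6 of 15 alternatives (lowest adjusted p = 0.00404). Genes of denervated muscle rose in 5 of 23, and in 6 adjusted over the list alone (median 0.25, and 0.38 without WT PBS replicate 1; adjusted p = 0.00728; adjusted p = 0.253 with an estimated correlation). Chrng was at 2.78, Runx1 at 2.15 and Ncam1 at 1.06. Apoptosis and p53 target genes rose in 5 of 25, and in 7 adjusted over the list alone (median 0.29, adjusted p = 0.000246; adjusted p = 0.105 with an estimated correlation). Pmaip1 was at 4.29 and Cdkn1a at 1.48. Chemokine and cytokine genes rose in 3 of 26, and in 14 adjusted over the list alone (adjusted p = 1.27e-06; adjusted p = 0.337 with an estimated correlation). Inflammasome and toll-like receptor genes rose in 4 of 27, and in 6 adjusted over the list alone (median 0.81, adjusted p = 2.73e-10; adjusted p = 0.168 with an estimated correlation). Of the list members named here, Col4a4, Mmp14, Ncam1 and Runx1 lost the call in 3 alternatives each, and Cdkn1a, Irf7 and Postn in 2 each. Besides these groups, the metallothionein gene Mt1 rose (2.02, SE 0.37; call lost in 3 alternatives), and the basement membrane genes Col4a3 (−1.64, SE 0.27) and Col4a4 (−1.12, SE 0.20) fell.

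Fast fibre genes (median −0.58, adjusted p = 0.000114), glycolysis and glycogen genes (−0.42, adjusted p = 1.16e-05), oxidative phosphorylation genes (−0.37, adjusted p = 4.2e-12) and mitochondrially encoded genes (−0.52, adjusted p = 7.12e-07) were lower as lists in dyW PBS. No member of these 4 lists passed in edgeR by itself, 0 also adjusted over the list alone, and the lists gave adjusted p = 0.383, 0.348, 0.337 and 0.226 with an estimated correlation. By limma on log2(RPKM + 0.1) the medians kept their sign and were −0.17, −0.15, −0.07 and −0.21. The fast fibre median was −0.88 without WT PBS replicate 1, and the glycolysis median −0.26 without dyW PBS replicate 1. Slow fibre genes are read with care here, since WT PBS replicate 1 stood apart: Myh7 was at 442 RPKM in it and at 0.0638 and 0.0207 in the other WT PBS libraries. Myh7 accordingly had a log2 fold change of −6.55 (SE 2.45, adjusted p = 0.218), and of 4.91 without that library (adjusted p = 0.0277), while DESeq2 called it lower (−6.55, adjusted p = 0.0339). Over all settings its adjusted p ranged from 0.0277 to 0.917. The median of the slow fibre list was −1.76, and 0.31 by limma on log2(RPKM + 0.1), while camera gave the list as higher without passing (adjusted p = 0.809). Without WT PBS replicate 1 the list was higher in dyW PBS (median 1.45, adjusted p = 6.32e-10; adjusted p = 0.154 with an estimated correlation).

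The genes called in PBS mice were mostly those of the untreated cohort. Of 14673 genes tested in both cohorts, which share no library, 343 were higher in both where 90.2 would be expected from the margins, 39 were lower in both (10.4 expected) and 0 changed in opposite directions. Of the 408 genes called in the PBS mice and tested in both, 405 (99.3%) had the same sign in the untreated cohort, and the log2 fold changes of all genes correlated across genes at r = 0.62. The number of calls in the PBS mice depended on the libraries: it was 129 without dyW PBS replicate 1, 177 without dyW PBS replicate 2, 177 without WT PBS replicate 2 and 125 without WT PBS replicate 3. It was 840 with DESeq2, 877 with limma on log2(RPKM + 0.1), which moved the median of all genes from −0.03 to 0.25, and 193 when only the 2 groups were fitted.

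**Figure D2:**
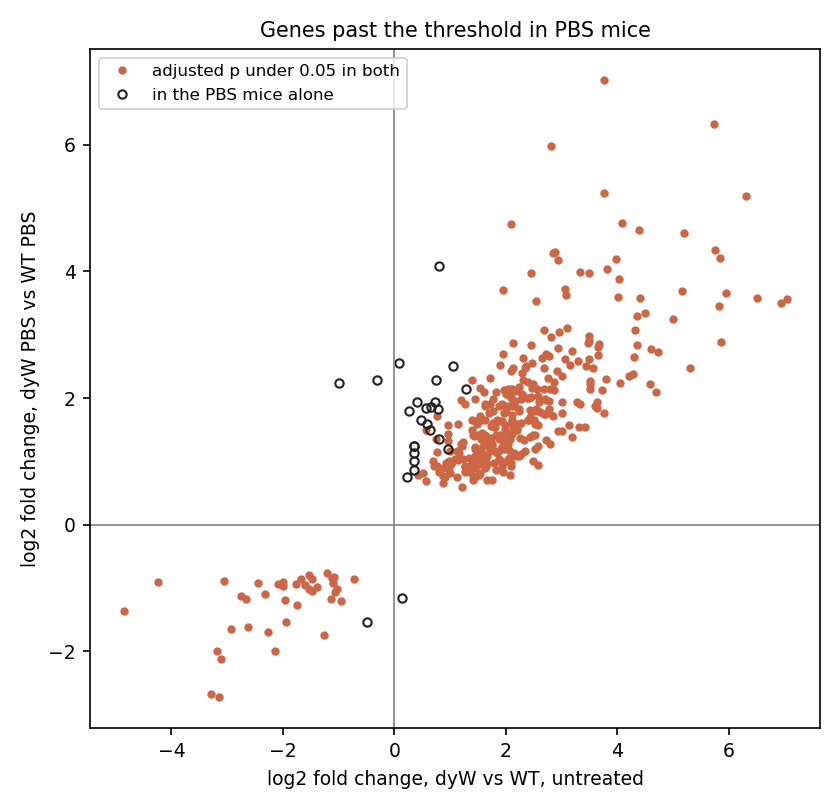
Log2 fold changes of the genes past the threshold in dyW PBS against WT PBS (vertical axis) against those in the untreated cohort (horizontal axis), 1 point per gene tested in both. Of the 408 genes, 405 have the same sign on both axes.

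The difference between the genotype effects of the cohorts was tested directly over 15771 genes, and 189 had a higher and 83 a lower log2 ratio of dyW to WT in the PBS mice than in the untreated mice. The majority turned under another scaling, with 41 higher and 68 lower by limma on log2(RPKM + 0.1) and 51 and 96 on log2(RPKM + 1). Perinatal Myh8 (difference −2.81, SE 0.48) and Myl4 (−2.35, SE 0.42), whose rise was smaller in the PBS mice, were among the lower ones, as were Lpcat2 (−3.27, SE 0.45), the chemokine gene Cx3cl1 (−2.45, SE 0.40) and Mamdc2 (−1.67, SE 0.29). Among the higher ones were the glycogen gene Ppp1r3c (2.08, SE 0.34), the insulin receptor substrate gene Irs1 (1.71, SE 0.28), Htra4 (3.39, SE 0.55), Tmtc1 (2.07, SE 0.36) and Osgepl1 (0.96, SE 0.17). Each of these 10 calls was lost in 4 to 9 of 21 alternatives. Embryonic fibre genes had a median difference of −0.98, with 4 of 24 lower and 11 adjusted over the list alone (adjusted p = 4.39e-06; adjusted p = 0.743 with an estimated correlation). Ribosomal protein genes had one of −0.52, with 0 of 78 past the threshold in edgeR and 0 adjusted over the list alone (adjusted p = 2.49e-09; adjusted p = 0.743 with an estimated correlation). Slow fibre genes had a median difference of −3.83, in which WT PBS replicate 1 takes part, with 2 of 17 lower and 15 adjusted over the list alone (adjusted p = 4.28e-06; adjusted p = 0.743 with an estimated correlation). The differences rose with log2 exon length across genes (r = 0.20). Lgals3 (−1.64, SE 0.42, adjusted p = 0.0567) and Lama2 (0.63, SE 0.35, adjusted p = 0.296) did not pass, but Lgals3 passed in 6 of 21 alternatives (lowest adjusted p = 0.00487). The count of 272 ranged from 0 to 637 when single libraries of the 4 groups compared were left out, and it was 0 without WT untreated replicate 3, dyW untreated replicate 3, dyW PBS replicate 2 or dyW PBS replicate 3. Age label, treatment with PBS and the number series of libraries and animals in the labels all differ between the cohorts and cannot be separated. A difference in handling or sequencing between the cohorts therefore cannot be told apart from age or PBS.

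The third comparison asks what TD139 changed in dyW muscle. No gene passed the threshold among 15331 tested by edgeR (0 genes; 583 at an unadjusted p under 0.05; smallest adjusted p = 0.888). DESeq2 on the 4 groups called 2 genes, Arrdc2 and Kbtbd13. DESeq2 on the dyW PBS and dyW TD139 libraries alone called 50, of which 31 were higher and 19 lower, and edgeR on those libraries and limma called 0. In the authors' own results 68 genes passed an FDR-adjusted p under 0.05, 41 higher and 27 lower. Of these, 67 were tested here, all with the same sign, and 48 had an unadjusted p under 0.05 here. Lgals3 was at 14.4 ± 1.86 RPKM in dyW TD139 against 16.9 ± 10.1 in dyW PBS (n = 3 each; log2 fold change −0.15, SE 0.32, adjusted p = 0.945), and without dyW PBS replicate 1 its log2 fold change was 0.35. Lama2 was at 0.940 ± 0.250 against 0.715 ± 0.0658 (0.45, SE 0.27, adjusted p = 0.888).

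The genes with the smallest p, none of which passed in edgeR (adjusted p = 0.888 each), had lower values after TD139 for the arrestin domain gene Arrdc2 (9.02 ± 3.62 RPKM in dyW PBS, 1.91 ± 0.408 in dyW TD139, n = 3 each, log2 fold change −2.22, SE 0.38), the cartilage collagen genes Col2a1 (−2.78, SE 0.75) and Col11a2 (−1.88, SE 0.46), Tbx6 (−1.58, SE 0.39) and Plp2 (−0.56, SE 0.14). They had higher values for the ubiquitin ligase adaptor gene Kbtbd13 (2.50 ± 0.259 and 4.96 ± 0.350 RPKM, log2 fold change 1.02, SE 0.20), Armcx4 (0.94, SE 0.20), the potassium channel gene Kcng4 (0.92, SE 0.21), Zfp770 (0.76, SE 0.19) and the ketone body enzyme gene Oxct1 (0.58, SE 0.15). Besides Arrdc2 and Kbtbd13, the 50 genes of DESeq2 on the 2 groups alone included Armcx4, Kcng4, Zfp770, Oxct1 and Tbx6. The libraries of Col2a1 overlapped between the groups (0.313 RPKM at the lowest in dyW PBS, 0.319 at the highest in dyW TD139).

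As lists, tendon and cartilage genes were lower after TD139 (median −0.90; 0 of 17 past the threshold in edgeR, 6 lower adjusted over the list alone; adjusted p = 6.72e-05; adjusted p = 0.802 with an estimated correlation). The median log2 level of this list, against the mean of all 18 libraries, overlapped between the groups. It was 0.62, 1.06 and −0.46 in the dyW PBS libraries and −0.44, −1.42 and −0.76 in the dyW TD139 libraries. Without any treatment it ranged from −0.74 to 0.74 over the untreated dyW libraries. Fmod, Cilp2 and Chad had log2 fold changes of −2.11 (SE 0.66), −1.88 (SE 0.64) and −2.53 (SE 0.88). Mitochondrially encoded genes were higher (median 0.42, 13 of 13 above 0; adjusted p = 6.54e-08; adjusted p = 0.773 with an estimated correlation). mt-Nd5 was at 0.80 (SE 0.29) and mt-Nd4l at 0.74 (SE 0.26). Fatty acid oxidation genes (median 0.39, adjusted p = 0.00196), oxidative phosphorylation genes (0.09, adjusted p = 0.00511) and slow fibre genes (0.77, adjusted p = 0.0155) were higher too, each with adjusted p = 0.919 with an estimated correlation. Without dyW PBS replicate 1 the fatty acid oxidation list did not pass (median 0.15, adjusted p = 0.25). Ppargc1a, the coactivator of mitochondrial genes, was at 0.93 (SE 0.30), Acadvl at 0.65 (SE 0.34) and Ndufs1 at 0.52 (SE 0.26); Myh7 was at 3.80 (SE 2.15), Myl2 at 3.16 (SE 1.77) and Myl3 at 2.83 (SE 1.75). Of these, DESeq2 on the 2 groups alone called Myh7 (adjusted p = 0.029) and Myl2 (adjusted p = 0.00367). Ribosomal protein genes were lower (median −0.26, and −0.12 without dyW PBS replicate 1; 1 of 78 above 0; adjusted p = 1.23e-08; adjusted p = 0.919 with an estimated correlation). Rpl10 was at −0.35 (SE 0.20) and Rpl27 at −0.41 (SE 0.24). Log2 fold changes of this comparison rose with log2 exon length across genes (r = 0.18). Proliferation genes were lower (median −0.39, adjusted p = 0.00254; adjusted p = 0.919 with an estimated correlation). Plk1 was at −1.02 (SE 0.40) and Aurkb at −0.90 (SE 0.43), and without dyW PBS replicate 1 this list turned to a median of 0.13 and did not pass (adjusted p = 0.819). In these lists other than tendon and cartilage, 0 members passed in edgeR by themselves, also 0 adjusted over the list alone.

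Mast cell and eosinophil genes were lower after TD139 (median −0.80, 0 of 6 above 0; adjusted p = 0.0023; adjusted p = 0.773 with an estimated correlation), with 0 members past the threshold in edgeR and 0 adjusted over the list alone. The list also passed without dyW PBS replicate 1 (median −0.68, adjusted p = 0.00363; adjusted p = 0.363 with an estimated correlation). Keratinocyte and hair follicle genes were lower (median −0.51, 0 of 7 above 0; adjusted p = 0.0124; adjusted p = 0.773 with an estimated correlation) and erythroid genes higher (median 0.34, 9 of 10 above 0; adjusted p = 0.0219; adjusted p = 0.919 with an estimated correlation). No member of these 2 lists passed in edgeR, 0 also adjusted over the list alone. Both kept their direction without dyW PBS replicate 1, at medians of −0.34 (adjusted p = 0.00335) and 1.66 (adjusted p = 2.97e-06), each with adjusted p = 0.33 with an estimated correlation. For erythroid genes this gives no separate support, since leaving out the highest dyW PBS library must raise the difference. Their median log2 levels were 1.4, −0.72 and −1.04 in dyW PBS and 1.4, 0.05 and 0.5 in dyW TD139 replicates 1, 2 and 3, so the groups overlapped. Macrophage genes had a median of −0.10 (11 of 31 above 0, adjusted p = 0.633), with Lyve1 at −1.04 (SE 0.40) and Cd14 at −0.67 (SE 0.30), and galectins and partners one of −0.11 (adjusted p = 0.616). Matrix and fibrosis genes had a median of −0.13 (9 of 47 above 0, adjusted p = 0.0219; adjusted p = 0.919 with an estimated correlation). Library dyW PBS replicate 1 weighed on these values: it had the lowest depth, 15.8 M exon reads, and the macrophage gene Cd68, chosen after its values were seen, was at 17.5 RPKM in it and at 8.14 and 6.46 in the other dyW PBS libraries. Without it the macrophage list was higher after TD139 (median 0.26, adjusted p = 0.00096; adjusted p = 0.669 with an estimated correlation), and the matrix list did not pass (adjusted p = 0.677).

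**Figure D3:**
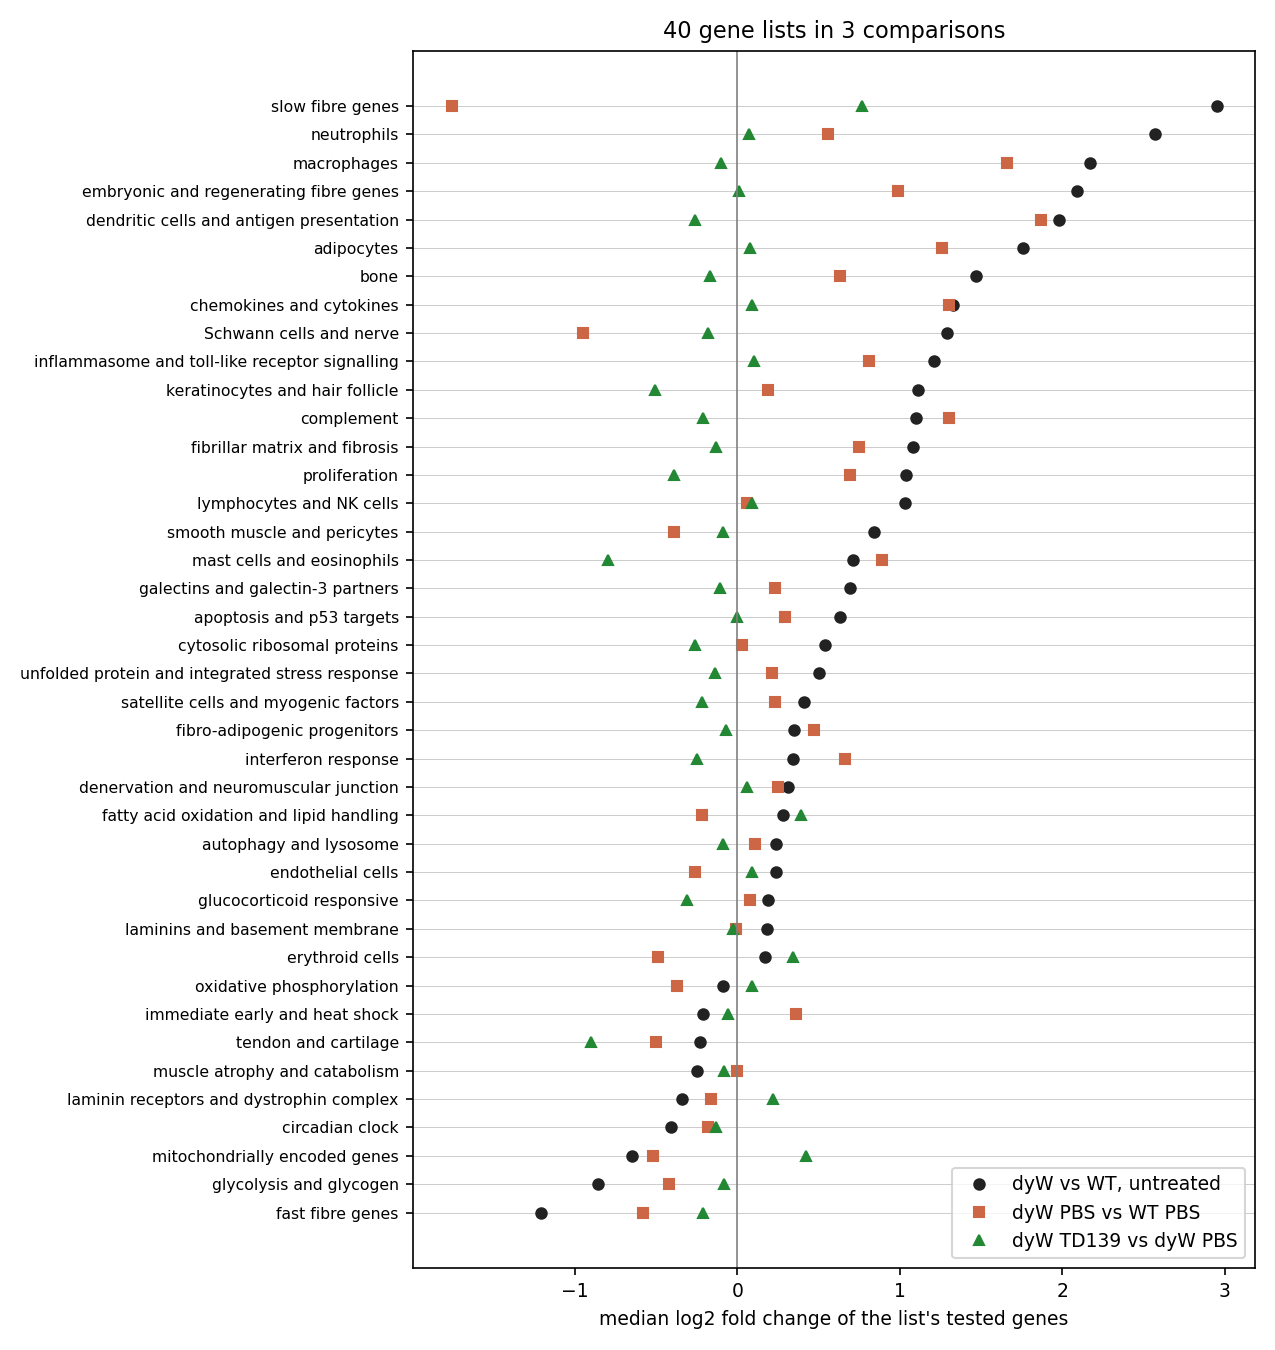
Median log2 fold change of the tested genes of each of 40 lists (horizontal axis) for untreated dyW against WT (circles), dyW PBS against WT PBS (squares) and dyW TD139 against dyW PBS (triangles), after TMM scaling. Macrophage genes lie at 2.17, 1.66 and −0.10; in the 3 comparisons the medians of 6, 8 and 4 lists change sign under another scaling, slow fibre genes in PBS mice among them.

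Genes higher in untreated dyW muscle had a median log2 fold change of −0.16 after TD139, with 1450 of 2053 tested below 0 (camera p = 1.7e-06; p = 0.295 with an estimated correlation). Genes lower in untreated dyW muscle had a median of 0.25, with 992 of 1362 above 0 (camera p = 3.03e-12; p = 0.179 with an estimated correlation). In dyW PBS against WT PBS the medians of these sets were 0.67 and −0.39, and in WT mice TD139 gave −0.10 and 0.14. Without dyW PBS replicate 1 the first median was 0.00 and the second 0.18. The slope of the TD139 effect on the untreated disease effect across 7325 genes was −0.10 (r = −0.37 across genes, which are not independent replicates), −0.03 without dyW PBS replicate 1, and −0.08 for TD139 in WT. By library it was −0.14, −0.15 and 0 in dyW TD139 replicates 1, 2 and 3, of which replicate 3 alone had Xist above the Y-linked Ddx3y. Log2 fold changes fell with log2 exon length in the untreated comparison (r = −0.22) and rose with it after TD139 in dyW (r = 0.18). Such opposite trends can enter the slope and the set medians, and their part was not tested. The disease score was −1.65 ± 0.43 in dyW PBS, −2.03 ± 0.31 in dyW TD139 (n = 3 each), −2.91 ± 0.34 in WT PBS (n = 3) and −3.09 ± 0.54 in WT TD139 (n = 2). The difference of −0.38 between dyW TD139 and dyW PBS had an exact two-sided permutation p = 0.2, where the smallest p this design allows is 0.1; it was −0.16 without dyW PBS replicate 1 and −0.59 without dyW PBS replicate 3.

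**Figure D4:**
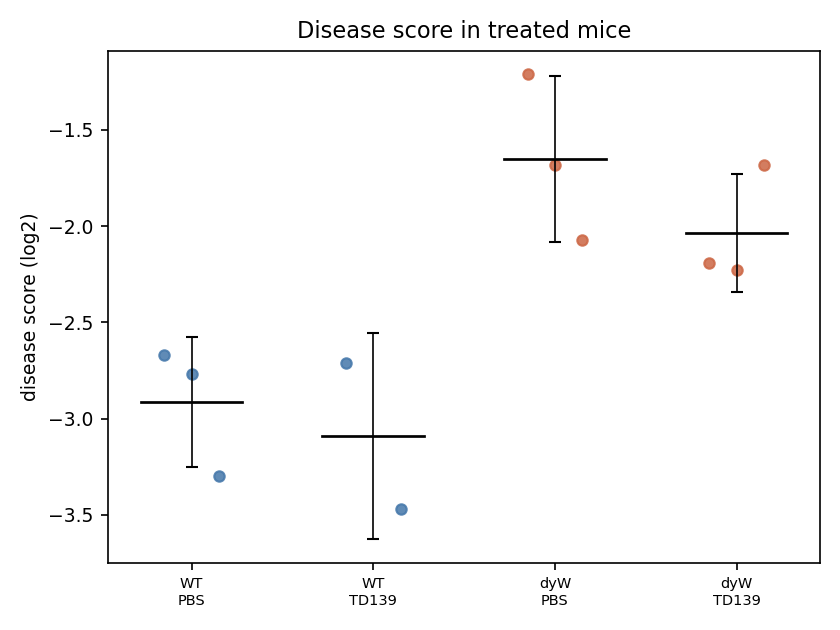
Disease score per library (points), group mean (long line) and SD (error bars) in the 4 groups of the treatment cohort, on a log2 scale. The dyW PBS libraries lie between −2.07 and −1.21 and the dyW TD139 libraries between −2.23 and −1.68, so the groups overlap, and the WT PBS libraries lie below both, between −3.30 and −2.67.

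In WT mice TD139 was compared with PBS to see its effect without the disease. No gene passed (0 genes by edgeR, 304 at an unadjusted p under 0.05, 3 by DESeq2), and with 2 WT TD139 libraries simulated log2 fold changes of 1 were called in 15% of cases. Lgals3 (0.03, SE 0.37) and Lama2 (−0.06, SE 0.29) had values near 0. The genes with the smallest p were, at lower values, Chad (−3.90, SE 1.08), the cartilage oligomeric protein gene Comp (−3.24, SE 0.91), the lubricin gene Prg4 (−3.11, SE 0.87), Dkk3 (−1.49, SE 0.41) and Arrdc2 (−1.48, SE 0.42), and at higher values Socs2 (1.23, SE 0.24), Gprc5c (0.95, SE 0.23), Tnfaip2 (0.89, SE 0.22) and Mtmr10 (0.59, SE 0.19), each with an edgeR adjusted p = 1. DESeq2 called Socs2 (adjusted p = 0.0441). The tendon and cartilage list was lower (median −1.76, 0 of 17 above 0; 0 past the threshold in edgeR and 7 lower adjusted over the list alone; adjusted p = 1.17e-19; adjusted p = 0.318 with an estimated correlation). Its median log2 levels were −1.79 and −0.51 in WT TD139 replicates 1 and 2, and 1.11, 1 and 0.15 in WT PBS replicates 1, 2 and 3. The size of this difference therefore rests in part on WT TD139 replicate 1. Macrophage genes had a median of 0.43 (28 of 31 above 0, adjusted p = 1.34e-06; adjusted p = 0.793 with an estimated correlation) and slow fibre genes one of −2.49 (adjusted p = 0.000132; adjusted p = 0.793 with an estimated correlation). Both rest in part on WT PBS replicate 1, without which the macrophage list had a median of 0.28 (adjusted p = 0.00836) and the slow fibre list turned to higher (median 0.30, adjusted p = 0.0182), each with adjusted p = 0.967 with an estimated correlation. Proliferation genes were higher in WT TD139 (median 0.52, 29 of 30 above 0; adjusted p = 2.13e-07; adjusted p = 0.793 with an estimated correlation), and less so without WT PBS replicate 1 (median 0.31, adjusted p = 0.0368; adjusted p = 0.967 with an estimated correlation). No member of these last 3 lists passed in edgeR, 0 also adjusted over the list alone.

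No gene passed the test of a difference between the TD139 effects in dyW and WT by edgeR (0 genes, 294 at an unadjusted p under 0.05, 1 by DESeq2). In simulated counts this test called 4% of log2 differences of 1 and 50.5% of those of 2. The smallest p belonged to Cpxm1 (−1.38, SE 0.35), Pim1 (−1.29, SE 0.38), Socs2 (−1.09, SE 0.32), Dio2 (1.90, SE 0.57) and Kbtbd13 (0.97, SE 0.30). Lgals3 differed by −0.18 (SE 0.49) and Lama2 by 0.51 (SE 0.39). Macrophage genes had a median difference of −0.56 (adjusted p = 9.61e-05; adjusted p = 0.888 with an estimated correlation), and proliferation genes one of −0.99 (adjusted p = 2.15e-09; adjusted p = 0.888 with an estimated correlation). Tendon and cartilage genes had a median TD139 effect below 0 in both genotypes, with a median difference of 0.47 (adjusted p = 0.00156; adjusted p = 0.888 with an estimated correlation). In these 3 lists 0 members passed in edgeR, and 0 adjusted over the list alone. Without dyW PBS replicate 1 the macrophage difference did not pass (median −0.16, adjusted p = 0.253), while proliferation (−0.36, adjusted p = 0.000258; adjusted p = 0.809 with an estimated correlation) and tendon and cartilage (0.57, adjusted p = 0.00303; adjusted p = 0.751 with an estimated correlation) did. Without WT PBS replicate 1 all 3 passed, at −0.43 (adjusted p = 0.00382), −0.75 (adjusted p = 7.42e-06) and 0.28 (adjusted p = 0.0377), each with adjusted p = 0.906 with an estimated correlation.

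TD139-treated dyW muscle was set against WT PBS muscle to see how much of the dyW profile was left. It still differed in 312 higher and 62 lower genes of 15331. Lgals3 was higher (2.50, SE 0.34, adjusted p = 0.00425), as were Krt8 (5.07, SE 0.56), Aldh3a1 (4.69, SE 0.70), Krt18 (4.30, SE 0.51), Mpeg1 (4.12, SE 0.32), Mt2 (3.94, SE 0.47), the small GTPase gene Rrad (3.73, SE 0.47) and Bcl2a1b (3.60, SE 0.67). Besides Lama2 (−2.22, SE 0.27, adjusted p = 0.00275), the lower genes included Chad (−4.56, SE 0.93), Col2a1 (−4.23, SE 0.79), Arrdc2 (−3.75, SE 0.40), the glutathione-degrading enzyme gene Chac1 (−2.99, SE 0.46), Col11a2 (−2.55, SE 0.47), Cd28 (−2.35, SE 0.47) and Vit (−2.34, SE 0.51). Of these, Chad, Col2a1, Arrdc2, Chac1 and Col11a2 also had lower values in dyW TD139 than in dyW PBS, without passing in edgeR. Of 15 alternatives, the call was lost in 8 for Vit (highest adjusted p = 0.15), 7 each for Cd28 and Bcl2a1b, 5 each for Chad and Col2a1 and 4 for Col11a2. Macrophage genes rose in 18 of 31, and in 25 with 1 lower adjusted over the list alone (median 1.47, adjusted p = 9.86e-21; adjusted p = 0.174 with an estimated correlation), matrix genes in 6 of 47, and in 16 with 1 lower adjusted over the list alone (median 0.55, adjusted p = 2.05e-06; adjusted p = 0.604 with an estimated correlation), and embryonic fibre genes in 12 of 24, and in 16 with 2 lower adjusted over the list alone (median 1.00, adjusted p = 6.68e-11; adjusted p = 0.0123 with an estimated correlation). With an estimated correlation the last call was lost without WT PBS replicate 1 (adjusted p = 0.134). The count of 374 was 1033 without WT PBS replicate 1, 96 to 130 without any other single WT PBS or dyW TD139 library, 860 with DESeq2 and 188 with the level of Xist as a term. The genes higher and lower in untreated dyW muscle had medians of 0.50 and −0.14 in dyW TD139 against WT PBS. In dyW PBS against WT PBS they had medians of 0.67 and −0.39. The slopes on the untreated disease effect were 0.29 and 0.39 in these 2 comparisons. Both comparisons use the same WT PBS libraries, so these gaps largely restate the TD139 effect in dyW and give no further support for it. Of 10 splits of the dyW libraries, the real one included, 3 gave a TD139 slope as far from 0.

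Sex labels and sex-linked transcripts were compared as a check of the labels. In the untreated cohort the higher of Xist and the Y-linked Ddx3y matched the sex label in each of 7 libraries. In the treatment cohort it did not match in 8 of 11 libraries, while Lama2 separated the genotypes, with at least 2.18 RPKM in WT and at most 1.10 in dyW. No gene tells TD139 from PBS, so the treatment labels could not be checked in this way. Xist was the higher transcript in dyW PBS replicates 2 and 3, dyW TD139 replicate 3, WT PBS replicates 1 and 2 and WT TD139 replicate 2. The labels give replicate 2 as female in both dyW groups. By these transcripts the sexes were not balanced between dyW PBS and dyW TD139, so sex is not fully separate from TD139 there. With the level of Xist as a term, 0 genes passed for TD139 in dyW by edgeR.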

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

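The tests of WT PBS replicate 1 and of the sex labels below, and the margin of 2 standard errors for Nnt, were chosen only after the results were seen, and the number of splits for the difference between cohorts and their reading were settled after a first draw. In the untreated dyW group (n = 4), 8 of 78 named genes had a library far from the other 3, measured as the gap to the nearest library over the range. Chance gives such a gap in about 1 in 20 groups. The ratio was 0.872 for Chil3 (0.482, 0.719, 1.34 and 7.19 RPKM), 0.85 for Amd1 (17.5 to 20.1 RPKM), 1 for Rsc1a1 (0 in 3 libraries and 0.683 in the other) and 0.839 for Ctss (72.9 to 137 RPKM). It was 0.951 for Lgmn (84.3 to 122 RPKM), 0.866 for Ppp1r3a (15.3 to 25.7), 0.849 for Cldn19 (1.24 at the lowest) and 0.914 for Pln (1.28 to 2.22).

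The genotype effect differed between the cohorts in 272 genes by a test of the difference itself. The named ones were Htra4 (3.39), Ppp1r3c (2.08), Tmtc1 (2.07), Irs1 (1.71), Osgepl1 (0.96), Mamdc2 (−1.67), Myl4 (−2.35), Cx3cl1 (−2.45), Myh8 (−2.81) and Lpcat2 (−3.27). When the cohort labels were exchanged within each genotype, 4 of 100 splits gave as many genes, the real one included, and the highest other gave 753. In the other 3, PBS and untreated mice are spread unequally over the 2 genotypes, so an effect of cohort shared by both genotypes enters the difference, with a weight of 1.33 to 1.75 in size against 0 in the real split. These splits point to a structure of the libraries by cohort, and the share of 1 in 20 set beforehand decides nothing about chance in this design. The count was 0 without WT untreated replicate 3, so the difference is not firmly shown. Age label, treatment with PBS and a difference in handling or sequencing between the cohorts stay open as untested explanations.

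Other splits of the libraries were also refitted for the remaining comparisons of 2 groups with at least 3 libraries each, and not for the 2 comparisons that involve the WT TD139 libraries (n = 2). For untreated dyW against WT, only the real split of 35 gave as many as 7395 genes (1 split, highest other 2327). A share of 1 in 35 lies under 0.05 and is the smallest these splits can give, so it argues against chance without excluding it. The splits do not separate genotype from any other difference between the 2 groups. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. There the real and the highest other counts were 411 and 0 for dyW PBS against WT PBS (1 split as large), 374 and 0 for dyW TD139 against WT PBS (1 split), and 0 and 0 by edgeR for dyW TD139 against dyW PBS (10 splits; 583 genes at an unadjusted p under 0.05, 2 genes by DESeq2). For the effect of TD139 on the disease sets, 7 of 10 splits lay as far from 0 as the −0.16 of the genes higher in dyW (highest other 0.33), 2 of 10 as the 0.25 of the genes lower in dyW (0.33), and 3 of 10 as the slope of −0.10 (0.17).

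Differences between WT and dyW mice can also come from strain. Of 73 genes tested within 10 Mb of Lama2, 0 changed in the same direction in both cohorts by edgeR, against 381 of 14599 elsewhere (one-sided Fisher exact p = 1). At the share found elsewhere only a few of 73 genes would be called. The test therefore cannot decide whether a strain segment carried along with the targeted allele is a source of shared changes. Nnt, which is partly deleted in C57BL/6J, had log2 fold changes of 0.81 (SE 0.38, adjusted p = 0.106) in untreated mice and −0.69 (SE 0.50, adjusted p = 0.565) in PBS mice. The latter was 0.52 (SE 0.21, adjusted p = 0.187) without WT PBS replicate 1, which held 8.12 RPKM against 1.36 and 1.38 in the other WT PBS libraries. A substrain difference cannot be told apart from other causes, since 0.81 is not 2 standard errors away from a 2-fold change. No biological explanation was tested here.

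WT PBS replicate 1 stood apart from the other WT PBS libraries in slow fibre genes (median log2 difference 4.17), Schwann cell genes (2.04) and adipocyte genes (1.61), with Myh4 at −0.84. Its Lama2 level of 4.58 RPKM, against at most 1.10 in dyW libraries, argues against a dyW library under a WT label. Its depth of 35.2 M exon reads was the lowest of the WT PBS libraries (37.1 M in the next), but low library depth is argued against by the 3 WT libraries with fewer reads, whose slow fibre medians on the same scale were 1.81 (untreated replicate 1), 0.59 and 0.14 (WT TD139). A candidate explanation is another part of the limb with more slow fibres, nerve and connective tissue in the sample, for which the lowest of the 3 list medians, that of matrix genes, was 0.28. The slow fibre and Schwann cell lists are those by which the library stood out, so they give no separate support. Of other connective tissue lists, fibro-adipogenic progenitor genes had a median of −0.23 and tendon and cartilage genes one of 0.41. No biological explanation was tested.

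In the treatment cohort, sex-linked reads and sex labels differed in 8 of 11 libraries (5 of 5 WT and 3 of 6 dyW). Lama2 separates the genotypes in 1 of 462 arrangements of the labels, which argues against libraries exchanged among all mice of the cohort. Xist was above Ddx3y in 6 libraries against 4 female labels, so libraries exchanged among mice of the same genotype cannot alone account for it. Wrong sex entries stay open, and an exchange between TD139 and PBS mice of 1 genotype is not excluded.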

How the results depend on the processing

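Unique reads, the Xist term, untreated mice without dyW replicates 3 and 4, DESeq2 on 2 groups and the lists without single libraries were chosen after seeing the data. No paired analysis was possible because each mouse carries its own number and no number occurs in 2 groups. Of the named genes past the threshold, 74 of 78 kept direction and call in untreated mice under the alternatives run for each gene, which leave out the further fold cutoff, 26 of 43 in PBS mice, 10 of 16 in dyW TD139 against WT PBS, and 0 of 10 for the difference between cohorts. Where no other reason is given, the cause was not tested. A further fold cutoff, which leaves fewer genes by construction, gave 3485 genes in untreated mice. With DESeq2 the counts were 840 (dyW PBS against WT PBS), 860 (dyW TD139 against WT PBS), 1211 (difference between cohorts), 2 (TD139 in dyW; 50 on the 2 groups alone), 3 (TD139 in WT) and 1 (difference between TD139 effects). Limma on log2(RPKM + 0.1) and log2(RPKM + 1) gave 877 and 835 in PBS mice and 109 and 147 for the difference between cohorts, where it moved the median of all genes from −0.01 to −0.24 and −0.17. Fitting only the 2 groups gave 193 in PBS mice, and the Xist term 188 in dyW TD139 against WT PBS. With an estimated correlation the number of lists past the threshold went from 18, 25, 14, 17, 14, 22 and 13 to 0 (untreated), 1 (PBS mice), 0 (TD139 in dyW), 0 (TD139 in WT), 0 (difference between TD139 effects), 1 (dyW TD139 against WT PBS) and 0 (difference between cohorts), where the lists of PBS mice and of dyW TD139 against WT PBS, embryonic fibre genes, gave 0.0829 and 0.134 without WT PBS replicate 1, and the disease sets kept medians of −0.16 and 0.25 without passing. Leaving out single libraries of the groups compared gave 5792 to 7713 genes in untreated mice, 125 to 601 in PBS mice, 96 to 1033 in dyW TD139 against WT PBS and 0 to 637 for the difference between cohorts. The last was 0 without WT untreated replicate 3, dyW untreated replicate 3, dyW PBS replicate 2 or dyW PBS replicate 3, 2 without WT PBS replicate 1, 3 without WT untreated replicate 2, 4 without dyW untreated replicate 4, 53 without WT PBS replicate 2, 73 without dyW untreated replicate 2, and 412, 580, 532 and 637 without WT untreated replicate 1, dyW untreated replicate 1, dyW PBS replicate 1 and WT PBS replicate 3. The count for dyW TD139 against WT PBS was 112, 130 and 106 without dyW TD139 replicates 1, 2 and 3, and 1033, 108 and 96 without WT PBS replicates 1, 2 and 3. For TD139 in dyW the first disease set ranged from −0.28 to 0.00, the second from 0.16 to 0.36, the slope from −0.15 to −0.03 and the score difference from −0.59 to −0.16. The sign reversed for Myh7 in PBS mice (4.91 without WT PBS replicate 1, lowest −7.13) and for genes near 0. These were Lgals3 for TD139 in dyW (0.35 without dyW PBS replicate 1, lowest −0.42), Lgals3 for TD139 in WT (−0.01 and −0.03 with limma, 0.00 with the Xist term, −0.19 without WT PBS replicate 3, −0.01 without WT TD139 replicate 1, highest 0.30), Lama2 for TD139 in WT (0.01 without WT PBS replicate 1, 0.37 without WT TD139 replicate 1, lowest −0.67) and Lgals3 for the difference between TD139 effects (0.32 without dyW PBS replicate 1, 0.04 without WT PBS replicate 3, lowest −0.45). Depth was lowest in dyW PBS replicate 1, at 15.8 M exon reads.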
